A study of Mus musculus with 6 samples.

How the data were processed

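The series covers mouse muscle satellite cells, the resident stem cells of skeletal muscle, in 2 states. Polyadenylated RNA was sequenced from freshly isolated satellite cells (FISC) and from activated satellite cells (ASC, cultured for 36 h), each as 1 wild-type (WT) library and 1 library labelled iKO for Yy1. In addition, 1 chromatin immunoprecipitation library for YY1 and 1 input library were made from ASC. Each of the 6 samples was its own group, so there were no replicates, and all comparisons describe these libraries without p-values or standard errors.

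The deposited expression values are FPKM, fragments per kilobase of transcript scaled to library size, per the file headers. There was 1 table for the FISC pair and 1 for the ASC pair. The submitters' processing notes name TopHat2, Cufflinks 2.2.1, MACS2 2.1.0 and the build mm9, without saying which served which step. The annotation, the strand setting, filters and any scaling between libraries are not given in the sources used here. Columns were matched to libraries by the state in the table's name and by the wild-type or knockout name in the column header. The table for FISC listed 24205 genes and that for ASC 24312, with 24067 symbols in both. No symbol was repeated within a table. The locus given for a gene differed between the tables for 175 symbols. None of the 13 protein-coding genes of the mitochondrial genome had an entry.

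FPKM removes library size, and total depth is unknown. The relative depth within a pair was read from the steps of low values, which are multiples of what 1 read is worth. Among 1542 FISC genes with at most 0.3 FPKM in both libraries, 27.9% shared a step that puts the iKO library at 1.00 reads per WT read. In ASC, 19.1% of 1573 such genes shared a step at 0.666 reads per WT read, so the WT library was 1.50 times as deep. No interval or detection floor was computed for FPKM. A gene at exactly 0 is described as listed at 0, and no fold is given against it.

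For the immunoprecipitation the authors deposited 1 list of 2031 peaks in the narrowPeak layout, called from 1 library with 1 input. The deposited score is a whole number equal to the truncated 10-fold −log10 p, as checked on the values. The deposited fold is the enrichment over the local background by the authors' peak caller. The authors' −log10 p and −log10 q of each peak were used to rank and filter, and the deposited summit offset gave the peak's position. The lowest −log10 p in the list was 4.02. Peak names were numbered up to 20534, and how the list was reduced is not given in the sources used here. Scores, folds and q are the authors' own values for this list.

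Ratios were computed as log2((FPKM + 1)/(FPKM + 1)), iKO over WT, for genes with at least 1 FPKM in at least 1 of the 2 libraries. The pseudocount of 1 understates the ratio of low genes. A gene was counted as higher or lower when the ratio of FPKM + 1 was at least 2-fold, a rule of size and not a test. For activation, the ASC library was set against the FISC library of the same genotype after scaling both to the same sum of FPKM. Those 2 libraries come from tables that may have been normalized separately, so the activation values are description only. The difference between states was the ASC ratio minus the FISC ratio.

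A total of 34 gene lists covered energy metabolism, mitochondria, ribosomes and proteasome, the cell cycle, satellite cell states, stress, signalling, matrix and markers of other cell types. The median ratio of a list with at least 3 measured members was placed among 10000 random lists of the same size, matched on expression in 20 bins. A list is said to stand apart when its median lies outside the central 95% of these random medians, that is below percentile 2.5 or above percentile 97.5. The lists, the rules, the named-gene rule and the alternatives were fixed before the data were examined, apart from those said in the text to have been chosen later.

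The genes named for each iKO comparison were the 10 with the highest and the 10 with the lowest log2 ratio among genes with at least 5 FPKM in the higher library, and for activation the 5 highest and the 5 lowest. Symbols that start with Mir, Snor, Rnu, Rny, Scarna, Rn45s, LOC, a digit, or Gm and a digit, or that end in Rik, were left out of naming but not of counts. Of each list, the 2 highest and 2 lowest members with at least 1 FPKM were eligible, and every member of the glycolysis list. Of the peaks, the 5 with the highest score and those at the named genes were eligible. Genes outside this rule are said to have been chosen after their values were seen.

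The tables give no strand. The planned distance to a transcription start site was therefore replaced by the distance to either end of the gene locus in the deposited tables, with 2 kb as the window. Near shares were compared with those of the same peaks moved by 100 and 200 kb to either side, and carry exact Clopper-Pearson 95% intervals that cover counting error only. A gene with a peak within 2 kb of either locus end is called bound, and bound genes were set against 10000 random gene sets matched on expression. No genome sequence was used here, so the planned motif counts were not made. Gene coordinates are those of the deposited tables on mm9, written from 1. Of 23133 symbols matched to RefSeq genes, 8595 had a listed locus of the same length as the RefSeq gene, and 541 differed by 1 bp. The reasons for the other differences were not examined. Some symbols share a listed locus that holds several genes. Locus length and locus ends are therefore those listed and need not be those of the single gene.

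The calculations ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and the plots in matplotlib 3.10.9. They were tested on simulated libraries built from the real values. In the FISC simulation on 11157 genes, the 2-fold rule recovered 100% of planted 4-fold changes and 41% of planted 2-fold changes, and called 0.0548% of unchanged genes. In the ASC simulation on 12409 genes it recovered 88% and 45%, and called 23.8% of unchanged genes, because the real spread across genes was treated as noise. In both simulations the noise was normal and equal at all expression levels, scaled to the median absolute deviation of the real ratios. It lacks the tails of the real ratios, so 0.0548% and 23.8% are not false-call rates of the real counts. Planted 2-fold changes lie at the threshold, which limited their recovery beforehand. Random lists of 30 genes stood apart in 4% of draws in both simulations, and lists shifted by a planted amount stood apart in 100% of FISC draws and 78% of ASC draws. The first rate follows from how the lists were drawn and does not cover lists of genes that vary together. The planted shift was larger than any FISC median of the planned lists, so recovery of smaller shifts was not measured.

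The alternatives were pseudocounts of 0.1 and 5, no filter, a filter at 5 FPKM, median-centred ratios, upper-quartile scaling, thresholds of 1.5-fold and 4-fold, the mean of a list, 5 expression bins, windows of 1 and 5 kb and the higher-scoring 1015 peaks. Chosen after seeing the data were matching on locus length as well as expression (in 100 cells), ratios centred within deciles of locus length, peaks with q of 0.05 or less, the list without the chrY peaks, libraries without small RNA genes or without Mir762, and the glycolysis list with Eno1 and its near-identical copy summed.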

Results

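RNA from 4 satellite cell libraries was compared, WT and Yy1 iKO in the freshly isolated state and WT and Yy1 iKO after 36 h in culture, together with 1 list of YY1 peaks from activated cells. The libraries listed between 10657 and 10947 genes at 1 FPKM or more. FPKM sums were 545755 and 531371 in the WT and iKO libraries of FISC, and 505469 and 1245942 in those of ASC. Mir762, a microRNA gene singled out after its value was seen, was listed at 496241 FPKM in the ASC iKO library, 39.8% of that sum, and at 0 in the ASC WT library. There was 1 library per group, so no difference below has a replicate check.

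The Yy1 transcript itself, encoding a zinc finger transcription factor, was lower in both iKO libraries. On chromosome 12 at 110031521 to 110054842 (mm9), Yy1 stood at 51.0 FPKM in the WT and 20.1 FPKM in the iKO library of freshly isolated cells, a log2 ratio of −1.30 and 2.46-fold lower with 1 added to each value. After activation it stood at 55.2 FPKM in the WT library and 2.03 FPKM in the iKO library, a log2 ratio of −4.21. That made Yy1 the lowest of all named genes in ASC, 18.6-fold lower on the same scale.

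The freshly isolated pair compared the genotypes before culture, with Yy1 lower but still at 20.1 FPKM in the iKO library, a weaker contrast than in ASC. Chemokines that attract neutrophils were lower in the iKO library: Cxcl3 (chromosome 5, 91215127 to 91217119) stood at 104 FPKM in WT and 8.19 in iKO, Cxcl5 at 35.0 and 2.99, and Cxcl2 at 258 and 70.1. Lower beside them were Il1r1, the interleukin-1 receptor (104 and 29.2 FPKM), Tnfaip2, a gene induced by tumour necrosis factor (54.5 and 15.6), Gbp5, an interferon-induced GTPase (36.9 and 10.9), and Il15ra, an interleukin-15 receptor chain (18.9 and 5.64). Panx1, a channel protein, was at 21.8 and 6.42 FPKM, Plbd1 at 7.08 and 1.81, and Glycam1 at 5.08 and 0.521. Higher in the iKO library were P2ry14, a receptor for UDP-sugars whose listed locus also holds Med12l and other genes (2.43 and 26.6 FPKM), Apod, a lipocalin (15.4 and 60.3), Adh1, an alcohol dehydrogenase (5.18 and 23.1), and Rpph1, the RNA of ribonuclease P (5.30 and 21.3). Cfd, an adipocyte-secreted protease, was listed at 0 in WT and stood at 8.43 FPKM in iKO. The other genes with the highest ratios, Eif3j1, Rps27, Rnaset2a, Amd2 and Eno1b, have near-identical copies or share a locus with another gene.

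Few genes differed by 2-fold in freshly isolated cells. Of 11229 genes, 76 were higher and 81 were lower in the iKO library, and the spread of the log2 ratio across genes was 0.39 (SD across genes, not replicates). Of 33 lists with a value, 7 stood apart on the higher and 4 on the lower side, where lists of unrelated genes would give 1.65 on both sides together. Genes of a list can move together between any 2 libraries, and some lists share members, so the excess does not measure an effect of Yy1. Matched on locus length as well, 5 and 3 stood apart, and the calls for heat shock (percentile 96.8), erythroid (96.7), fibroblast (3.0) and glycolysis genes (3.45) given below were lost, while mitochondrial ribosomal proteins (median −0.07, percentile 2.72) came to stand apart on the lower side (1.78). Interferon response genes had a median of −0.33, below all 10000 random lists, with 16 of 18 members below 0. Gbp2 (80.3 and 30.4 FPKM) was at least 2-fold lower, and Ifit1 stood at 6.67 and 2.97. Collagen and matrix genes had a median of −0.31 (percentile 0.01), 26 of 27 below 0 and all within 2-fold, among them Timp1, a protease inhibitor (74.3 and 41.9 FPKM), and Col1a1 (68.6 and 42.9). Fibroblast markers moved the same way at the edge of the random range, with a median of −0.24 (percentile 2.5), although Dcn stood at 104 and 144 FPKM.

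Immediate early genes, whose transcription follows stimulation within minutes, had a median of 0.27 in freshly isolated cells, above all 10000 random lists. Of these 24 genes 18 were above 0 and none passed 2-fold, with Jund at 307 FPKM in WT and 430 in iKO and Fosl1 the other way at 127 and 78.1. Genes of G1/S and DNA replication had a median of 0.18 (percentile 99.2), with Rfc4, a clamp loader subunit, at 4.20 and 8.07 FPKM and the helicase subunit Mcm5 the other way at 4.34 and 1.93. The p53 targets had a median of 0.15 (percentile 99.8), including Trp53inp1 (11.1 and 17.2 FPKM), while Fas, a death receptor, stood at 291 and 196. Smaller still were the shifts of respiratory complex I (0.08, percentile 99.98), cytosolic ribosomal proteins (0.07, above all random lists) and heat shock genes (0.09, percentile 98.8), in which Dnajb1, a co-chaperone, stood at 1250 and 1858 FPKM. Glycolysis genes had a median of −0.15 (percentile 2.4), with Slc16a3, a lactate exporter, at 29.9 and 19.3 FPKM and Pfkp at 50.4 and 34.8. This placement ended when Eno1 and its near-identical copy were summed (−0.07, percentile 25.3), and also with a pseudocount of 0.1 (3.31), no filter (6.05), a filter at 5 FPKM (2.98), upper-quartile scaling (2.57) and the mean (6.64).

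Signs of other cells and of RNA composition also differed within the freshly isolated pair. Erythroid genes had a median of 0.24 (percentile 99.68), with Hbb-bs at 85.5 FPKM in WT and 175 in iKO but Hbb-b1 at 85.5 and 35.4; the table places both at the same locus, so the split between them is uncertain. Markers of endothelial cells (−0.19), immune cells (0.04), pericytes (−0.01, and 0.03 under upper-quartile scaling), tenocytes (0.20) and Schwann cells (−0.03) did not stand apart. The ribosomal RNA precursor Rn45s was at 379 FPKM in WT and 1289 in iKO, and Lars2 at 142 and 472, both chosen after their values were seen. Rmrp, chosen in the same way, was at 9.48 and 30.6 FPKM, and Rpph1, named above, was also higher. Of small RNA genes, among them Rn45s, Rmrp and Rpph1, 11 were at least 2-fold higher and 4 lower. The rise of Rpph1 may thus belong to a difference in RNA composition, which was not tested. Ddx3y, carried by the Y chromosome and also chosen later, was at 62.1 and 28.3 FPKM in FISC and listed at 0 in both ASC libraries, while Xist, chosen in the same way, was at 62.3 and 65.4 in FISC and had a log2 ratio of −1.61 in ASC. A difference in the animals' sex between the states, or in the share of male cells within the FISC pair, was not tested. Such a difference cannot be separated from activation or genotype in these libraries.

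**Figure D1:**
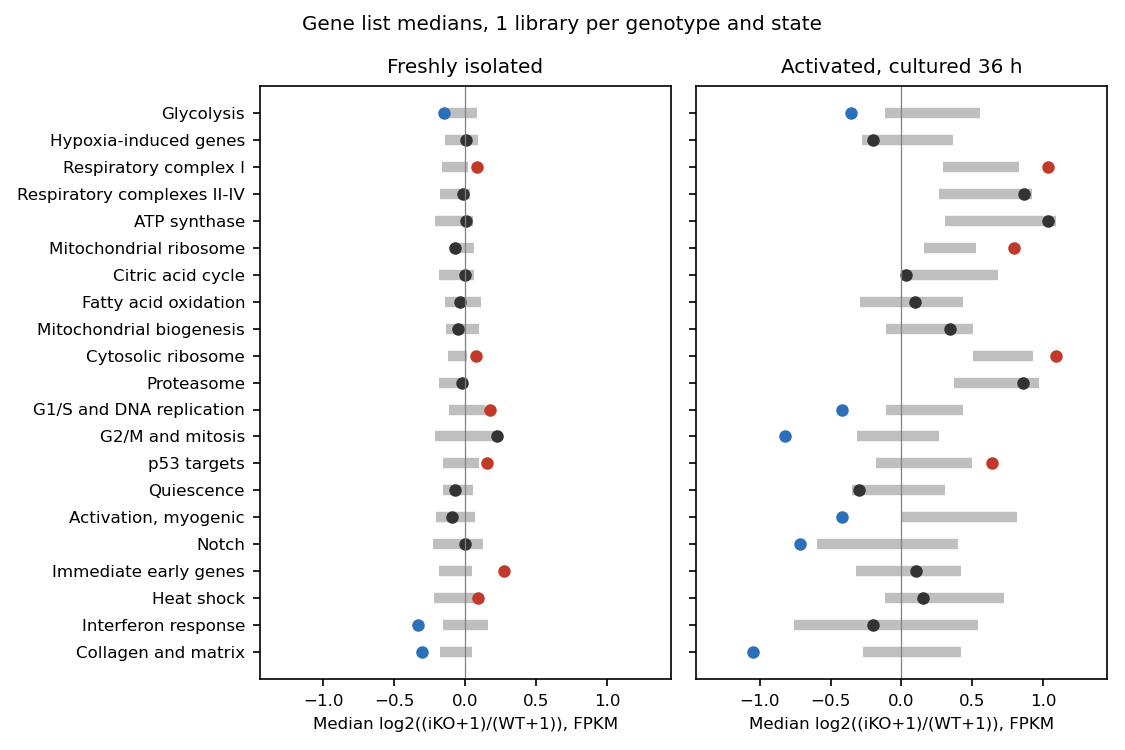
Median log2((iKO+1)/(WT+1)) of FPKM for 21 gene lists in freshly isolated (left) and activated (right) satellite cells, with grey bars for the central 95% of 10000 random lists matched on expression. Red and blue points lie above and below that range, as complex I at 1.03 and G2/M genes at −0.82 in activated cells.

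In activated cells the question was which parts of metabolism and the cell cycle differ without Yy1. The glycolysis list stood apart on the lower side, with 2 of 26 members at least 2-fold lower, and the lists of complex I and of ribosomal proteins stood apart on the higher side. Slc16a3 (chromosome 11, 120809798 to 120820314) stood at 13.7 FPKM in WT and 2.69 in iKO, and, within 2-fold, Tpi1, triosephosphate isomerase, at 185 and 98.6 and Gapdh at 1033 and 736. Ndufa2, a complex I subunit (chromosome 18, 36894724 to 36904241), stood at 180 and 747 FPKM. Pax7, the transcription factor that marks satellite cells (chromosome 4, 139293996 to 139388883), was at 28.3 FPKM in WT and 6.19 in iKO. Of 11215 genes 980 were at least 2-fold higher and 926 at least 2-fold lower, and the spread across genes was 0.80. Upper-quartile scaling moved the median of all genes by −0.12 and gave 664 higher and 1226 lower genes.

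Of the glycolysis list, 22 of 26 measured genes had a ratio below 0 in activated cells. The median was −0.36 (percentile 0.03), when the central 95% of matched random lists ran from −0.12 to 0.56. Slc16a3 and Eno1, an enolase, were at least 2-fold lower and no member was 2-fold higher. Eno1 (chromosome 4, 149611306 to 149622982) stood at 1032 FPKM in WT and 289 in iKO, while its near-identical copy Eno1b went from 0.869 to 371; their sum was 1033 and 660 FPKM, 1.56-fold lower. Below 0 but within 2-fold were the hexokinases Hk1 (45.9 and 25.2 FPKM) and Hk2 (18.2 and 10.2), Pfkfb3, a regulator of phosphofructokinase (5.97 and 2.96), Pdk1 (2.78 and 1.51) and the glucose transporter Slc2a1 (39.9 and 27.0). Closer to WT were Ldha at 846 and 706 FPKM, Aldoa at 609 and 487, Pgam1 at 245 and 198 and Pkm at 1382 and 1314. Pgk1 (482 and 491 FPKM), Pfkm (8.32 and 9.58) and Ldhb (14.5 and 22.0) lay above 0. Hypoxia-induced genes, many of which share a regulator with glycolysis, did not stand apart (median −0.20, percentile 6.7): Adm stood at 17.4 and 5.54 FPKM and Higd1a at 25.6 and 64.0.

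**Figure D2:**
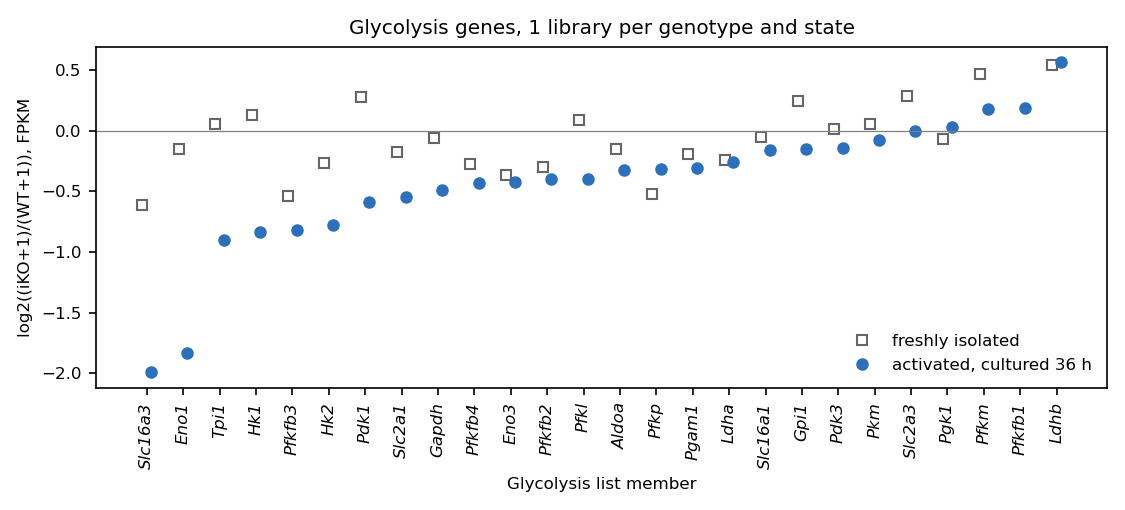
Log2((iKO+1)/(WT+1)) of FPKM for each measured glycolysis gene, as open squares in freshly isolated and filled circles in activated cells, 1 library per genotype and state. In activated cells 22 of 26 genes lie below 0, Slc16a3 lowest at −1.99 and Ldhb highest at 0.56.

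Complex I of the respiratory chain had a median of 1.03 in activated cells (percentile 99.99), with 22 of 37 members at least 2-fold higher and none lower. Ndufa7 stood at 180 FPKM in WT and 551 in iKO, whereas the large subunit Ndufs1 stood at 66.5 and 62.1. Complexes II to IV had a median of 0.86 with 12 of 27 members 2-fold higher, and ATP synthase 1.04 with 9 of 17, but neither stood apart from lists of like expression (percentiles 93.8 and 96.0). In them, Cox6c (298 and 846 FPKM), Cox7c (355 and 981), Atp5l (292 and 854) and Usmg5 (286 and 874) were higher, while Sdha (118 and 115), Uqcrc1 (153 and 149), Atp5a1 (472 and 361) and Atp5b (796 and 732) were not. Mitochondrial ribosomal proteins had a median of 0.79, above all random lists, and 24 of 76 were 2-fold higher, including Mrps21 (86.8 and 304 FPKM) and Mrpl33 (201 and 604). Genes of the citric acid cycle, also mitochondrial, had a median of 0.03 (percentile 3.5), and fatty acid oxidation genes 0.10 (percentile 58.1), which upper-quartile scaling turned to −0.11 and −0.04. Suclg2 stood at 29.7 and 8.40 FPKM, Idh2 at 66.0 and 36.8 and Suclg1 at 71.0 and 125. Ppargc1b and Pprc1, coactivators of mitochondrial gene expression, stood at 2.67 and 0.485 and at 47.2 and 26.3 FPKM in a mitochondrial biogenesis list with a median of 0.34 (percentile 81.5).

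The same direction held for cytosolic ribosomal proteins, with a median of 1.09 above all random lists and 55 of 77 members 2-fold higher, such as Rpl38 (1860 and 5588 FPKM) and Rps3a1 (697 and 2126). Proteasome subunits had a median of 0.86 without standing apart (percentile 86.0), but did so among lists also matched on locus length (98.8), with Psmb6 at 193 and 521 FPKM. The ratio in activated cells moved with the length of the listed gene locus, which some symbols share. Across 11215 genes the correlation of the log2 ratio with log10 locus length was −0.40 (Pearson) and −0.44 (Spearman), genes not being independent replicates. The shortest decile of genes, with a median locus of 2.81 kb, had a median ratio of 0.67, and the longest decile, at 184 kb, −0.48. In freshly isolated cells the corresponding medians were 0.04 and −0.04.

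**Figure D3:**
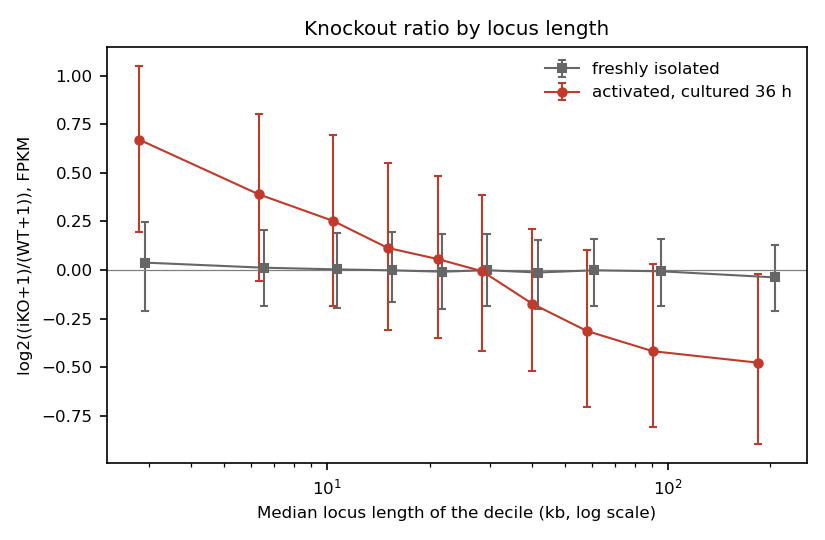
Median log2((iKO+1)/(WT+1)) of FPKM in deciles of locus length (x axis, kb, log scale), with bars from the lower to the upper quartile of the genes. The activated pair runs from 0.67 in the shortest to −0.48 in the longest decile, and the freshly isolated pair from 0.04 to −0.04.

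Lists of cell division genes stood apart on the lower side in the activated iKO library. The G2/M list had a median of −0.82, below all random lists, with 27 of 30 members below 0 and 12 at least 2-fold lower. Kif20a, a mitotic kinesin, stood at 16.7 FPKM in WT and 3.25 in iKO and Cenpe, a kinetochore motor, at 8.09 and 2.22, while Cdk1 (35.9 and 38.6) and Birc5 (62.7 and 74.9) did not follow. The G1/S and replication list had a median of −0.42, also below all random lists, and 5 of 36 members were 2-fold lower, including Pola1, a DNA polymerase subunit (18.1 and 5.97 FPKM), and Mcm5 (81.0 and 32.5). The p53 targets were higher, with a median of 0.64 (percentile 99.7) and 7 of 24 members 2-fold higher, led by Fas (2.83 and 11.1 FPKM) and the stress cytokine Gdf15 (28.3 and 83.6). Sesn2, in the same list, stood at 18.4 and 8.43.

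Of the lists for satellite cell states, myogenic activation had a median of −0.42 (percentile 0.01), with Six4 at 8.81 and 1.85 FPKM, Fgfr4 at 18.8 and 9.52 and the nucleolar Fbl higher at 312 and 673. Notch pathway genes had a median of −0.72 (percentile 0.77), with 9 of 11 below 0 and none 2-fold lower, including the ligand Jag2 (28.2 and 13.8 FPKM). Quiescence genes went both ways around a median of −0.30 (percentile 4.6, and 1.6 with locus length matched too, which is apart). Pax7 and Foxo3 (16.6 and 3.62 FPKM) were among the 7 that were 2-fold lower, and Cdkn1c (0.803 and 3.66) and Fos (1.76 and 4.59) were the 2 that were higher. Collagen and matrix genes had the lowest median, −1.05 with 12 of 23 members 2-fold lower, among them the laminin chain Lama2 (17.4 and 3.74 FPKM) and Fbn1, fibrillin (16.4 and 4.49). Differentiation genes had a median of 0.57 over the 12 measured (percentile 99.76, but inside the range of lists also matched on locus length), mostly at a few FPKM, as Tnnc1 at 0.505 and 2.73. Immune cell markers were higher in the same library at low levels, with a median of 1.31 over 4 genes (percentile 99.98), such as Cd14 at 2.80 and 9.75 FPKM and Cd68 at 1.36 and 5.16. Markers of fibroblasts (−0.28), pericytes (−0.71) and tenocytes (−0.25) did not stand apart, nor did heat shock (0.15), antioxidant (0.35), interferon (−0.20), cholesterol synthesis (−0.14) and immediate early genes (0.11), YY1 partners (−0.13) and the unfolded protein response (0.12, and −0.01 under upper-quartile scaling). Among these, the stress factor Ddit3 stood at 21.7 and 69.0 FPKM, superoxide dismutase Sod1 at 526 and 1656, Srebf2, a regulator of sterol synthesis, at 45.0 and 16.6 and Ep300, an acetyltransferase, at 14.4 and 7.42.

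The lowest single genes in activated cells included Peg3, an imprinted zinc finger gene (chromosome 7, 6658671 to 6683130; 32.1 FPKM in WT and 1.02 in iKO), Zbed6 (15.4 and 0.185), Vcl, which encodes the adhesion protein vinculin (17.4 and 0.611), Spred2, an inhibitor of Ras signalling (29.2 and 1.77), Clcn5, a chloride transporter (19.3 and 1.29), Tgoln2 (16.7 and 1.04) and Slfn9 (log2 ratio −3.51). The table gives Zbed6 and Zc3h11a the same locus, and likewise Tgoln2 and Tgoln1, so these ratios are uncertain. The highest included Map1lc3a, an autophagosome protein (13.1 and 71.5 FPKM), Krt18, a keratin (2.81 and 20.2), Dcxr, a carbonyl reductase (10.5 and 62.0), Nrp (0.697 and 8.34, uncertain because the table gives it the same locus as Alkbh1, Snw1 and Slirp) and BC051226 (1.40 and 11.1), and Snhg9 was listed at 0 in WT and stood at 11.1 in iKO. The ratios of Eno1b, Atp6v0c-ps2, Amd1, Eif3j1, Apoo-ps and BC002163 are uncertain, since near-identical sequences can exchange reads. Summed with its partner, Amd1 with Amd2 stood at 64.6 and 39.7 FPKM, Eif3j1 with Eif3j2 at 65.5 and 63.7, Apoo with Apoo-ps at 40.2 and 44.5 and Atp6v0c with its pseudogene at 156 and 339. Ndufs5 with BC002163 stood at 144 and 443. Map1lc3a, Krt18, Dcxr, BC051226 and Snhg9 lie in decile 1 of locus length, the shortest, which held 328 of the 980 higher genes. Vcl, Spred2 and Clcn5, like Pax7 above, lie in deciles 9 and 10, which held 176 and 218 of the 926 lower genes. Peg3, Tgoln2 and Slfn9 lie in shorter deciles. For single genes the trend with locus length was not separated from other differences.

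Few genes passed 2-fold in both states. Of 10251 genes measured in each, 22 were 2-fold higher in both iKO libraries where independent lists would share 4.64, and 10 were lower in both where 4.73 would be shared, among them Alpl, Ankrd49, Clmp, Clybl, Hmgb3, Il1r1, P2ry2, Spata24 and Yy1. In opposite directions, 9 were higher in FISC and lower in ASC (4.24 for independent lists) and 4 the reverse (5.17). The 9 include Amd2, Apoo-ps, Eif3j1 and Rps27, whose ratios are uncertain, and the small RNA genes Snora23, Snora28 and Snora64. The 22 include Eno1b, whose ratio is uncertain, and the small RNA genes Rmrp, Rpph1, Snora74a and Snora78. The shortest decile of locus length held 24 of the 76 genes higher in FISC and 328 of the 980 higher in ASC. The number for independent lists does not allow for this common tendency. Across genes, the FISC and ASC ratios had a Pearson correlation of 0.14 and a Spearman correlation of 0.18. The difference between states, ASC ratio minus FISC ratio, stood apart on the higher side in 7 and on the lower side in 7 of 33 lists, and in 5 and 10 with locus length matched too. It was 1.03 for complex I, 0.89 for complexes II to IV (at percentile 94.5 among lists also matched on locus length), 0.83 for mitochondrial ribosomal proteins and 1.02 for cytosolic ribosomal proteins. It was −0.16 for glycolysis (percentile 1.7, but 3.42 with 5 expression bins and so no longer apart), −0.81 for G2/M, −0.47 for G1/S, −0.54 for matrix and −0.34 for quiescence genes.

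Activation itself was described from the WT libraries of both states, which also differed in Ddx3y and in markers of other cells. One state was freshly isolated and the other cultured for 36 h. Effects of cell isolation, of culture and of cell composition cannot be separated from activation here, so the differences below are between these states. Proliferation genes were far higher after culture: all 30 G2/M genes were at least 2-fold higher, with a median of 3.82, as were 34 of 36 G1/S genes (3.36). Top2a, a DNA topoisomerase, stood at 0.644 FPKM in FISC and 71.1 in ASC, Ube2c at 0.473 and 56.7 and Rrm2, a ribonucleotide reductase subunit, at 5.18 and 216. Spp1, encoding the secreted protein osteopontin, went from 1.61 to 1154 FPKM and Hmga2, a chromatin protein, from 0.0870 to 55.4. Lower after culture were the metallothionein Mt2 (5662 and 11.1 FPKM), Fos (913 and 1.76), Fosb (709 and 2.67), the chemokine Cxcl1 (2474 and 6.86) and the chaperone Hspa1a (1083 and 3.37). Immediate early genes had a median of −4.28, with 22 of 24 at least 2-fold lower, quiescence genes −2.53 (24 of 31), heat shock genes −1.65 (9 of 15) and interferon genes −1.81 (16 of 18). Of the markers of other cells, erythroid (−6.38), fibroblast (−2.31), tenocyte (−2.05), Schwann cell (−1.98) and pericyte lists (−1.54) stood apart on the lower side, and endothelial (−1.14, percentile 2.5) and immune lists (−0.93, percentile 9.23) did not.

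Among metabolic genes, mitochondrial ribosomal proteins (median 1.92, 64 of 76 2-fold higher), the proteasome (1.76), complex I (1.36) and mitochondrial biogenesis (1.09) stood apart on the higher side after activation. So did complexes II to IV (1.09) and ATP synthase (1.20), though ATP synthase did not among lists also matched on locus length (percentile 96.8). Glycolysis genes split, 10 being 2-fold higher and 8 lower of 28 (median 0.65, percentile 75.7); the median was 0.15 after centring on all genes and 0.26 under upper-quartile scaling. Higher in ASC were Eno1 (102 and 1032 FPKM), Pgk1 (77.3 and 482), Pgam1 (37.1 and 245), Tpi1 (48.9 and 185), Pfkl (11.7 and 43.5) and Pkm (314 and 1382), and lower were Hk2 (77.2 and 18.2), Slc2a3 (16.3 and 4.08), Slc2a1 (98.4 and 39.9) and Eno2 (5.57 and 0.480). Of 11816 genes, 4015 were higher and 1880 lower after activation, around a median of 0.50; centred on that median, which lowers each list median by as much, 2337 were higher and 2897 lower, and under upper-quartile scaling 2696 and 2604. In the iKO libraries the median was −0.68, set by Mir762 in the sum, with 1488 higher and 4943 lower of 11797, with 2982 and 3042 after centring and 2728 and 3311 under upper-quartile scaling. In these libraries the G2/M and complex I lists lay above all random lists and glycolysis at percentile 20.8, Top2a being at 27.5 FPKM in activated iKO cells. Across 11476 genes the WT and iKO activation ratios had a Pearson correlation of 0.89.

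YY1 binding in activated cells was given as 2031 peaks with a median width of 112 bp, of which 350 (17.2%) had q of 0.05 or less. The highest-scoring peak near a gene lay beside Napepld (chromosome 5, 21207553 to 21207739, fold 24.4), followed by a peak at Madcam1 and Tpgs1 (chromosome 10, 79131842 to 79132301, fold 23.9). Among the genes named by rule, peaks had a fold of 13.4 at Psmb5 (chromosome 14, 55236784 to 55237142), 6.91 at Mrps27 and 6.31 at Usmg5, which shares that peak with Taf5. Eno1 had a peak 197 bp from its locus end (chromosome 4, 149610972 to 149611109, fold 6.68), and Zbed6, Fam162a, Tomm22 and Ndufa6 had peaks of fold 5.53, 7.23, 5.45 and 5.18. The 3 highest scores of all belonged to regions between 5 and 16293 on chromosome Y, with folds of 61.8, 58.7 and 41.0, ahead of the first listed gene of that chromosome at 61650.

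Peaks were more frequent near locus ends than shifted positions. Within 2 kb lay 622 of 2031 peaks, 30.6% (exact 95% interval 28.6% to 32.7%), against 8.94% of shifted positions, and of those with q of 0.05 or less 289 of 350, 82.6% (78.2% to 86.4%), against 14.4%. A further 633 lay deeper inside a locus and 776 outside any. The tables did not tell exons from introns. Mitochondrial ribosomal protein genes were bound in 22 of 76 cases, 28.9% (19.1% to 40.5%), above all 10000 random sets of like expression, which averaged 9.19%. Complex I genes were bound in 9 of 37 cases, 24.3% (11.8% to 41.2%, percentile 99.46). With peaks of q 0.05 or less, 12 of the 76 and 6 of the 37 genes were bound, where 384 of all 11215 measured genes were. These stricter counts were not set against random sets, and the random sets above were not matched on locus length. Proteasome genes, bound in 5 of 31 cases, did not stand apart (percentile 86.1). Bound were Eno1 of 26 glycolysis genes (percentile 28.4) and Aurka of 30 G2/M genes (percentile 26.2), both lists inside the central 95% of random sets; Aurka was named after its binding was seen.

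**Figure D4:**
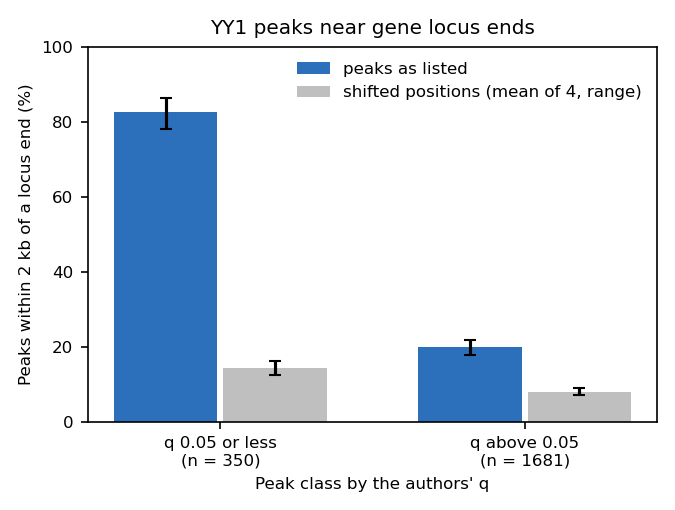
Percentage of YY1 peaks within 2 kb of either end of a gene locus, for peaks with q of 0.05 or less and above 0.05 by the authors' peak caller. Blue bars carry exact 95% intervals and grey bars show the mean and range of 4 shifted sets, 82.6% against 14.4% in the first class and 19.8% against 7.81% in the second.

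Bound genes were set against the iKO ratio. The 700 bound genes measured in activated cells had a median ratio of 0.05, inside the central 95% of random sets (percentile 19.8), and −0.07 under upper-quartile scaling. With peaks of q 0.05 or less, 384 bound genes had a median of 0.16, also inside it (percentile 96.4). Of the 700 bound genes, 80 (11.4%) were 2-fold higher, where random sets averaged 10.5%, and 56 (8%) were lower, where they averaged 6.63%. The 22 bound mitochondrial ribosomal genes had a median of 0.80 and the 54 others 0.76, and the 9 bound complex I genes 1.02 and the 28 others 1.12. In freshly isolated cells the 695 bound genes had a median of −0.02 (percentile 13.6), and 0.01 under upper-quartile scaling. Of these, 8 (1.15%) were 2-fold higher, where random sets averaged 0.542% (percentile 97.4, and 98.2 within 1 kb, 99.3 within 5 kb and 99.6 with q of 0.05 or less, which are apart), and 1 (0.144%) was lower, where they averaged 0.719% (percentile 2.1, but 3.19 with locus length matched too, 9.19 within 5 kb and 15.3 with q of 0.05 or less). These shares are uncertain, since the higher genes include Eif3j1, Rps27, Rn45s and Lars2 and the lower gene is Eif3j2, the copy partner of Eif3j1. With 1 immunoprecipitation and peaks mapped to either locus end, a bound gene need not be bound at its start site.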

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

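The results here were picked out because the difference between the iKO and WT libraries had opposite directions in the freshly isolated and the activated state. With 1 library per group, none of these differences was tested.

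Genes of G1/S and DNA replication stood on opposite sides of their random lists in the states, with a median ratio of 0.18 in FISC and −0.42 in ASC, a difference of −0.59. Many of these genes were listed at a few FPKM in freshly isolated cells, as Mcm5 at 4.34 FPKM in WT against 81.0 in the activated WT library.

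The remaining differences belong to genes that share their listed locus with another symbol, so the split of reads between the symbols is uncertain. The ASC ratio minus the FISC ratio was 5.51 for Amd1 and −5.02 for Amd2. It was −4.96 for Apoo-ps, −8.76 for Eif3j1 and −5.98 for Rps27. After summing each with its partner, a step chosen once these values were seen, the FISC and ASC ratios were −0.09 and −0.69 for Amd1 with Amd2, 0.01 and 0.15 for Apoo with Apoo-ps, −0.18 and −0.04 for Eif3j1 with Eif3j2, and −0.18 and 0.91 for Rps27 with Rps27rt.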

How the results depend on the processing

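Centring within deciles of locus length, peaks with q of 0.05 or less and sums without Mir762 were chosen after the data had been seen. Of 1530 recomputed values over 193 results, none reversed a direction that had been called, while values near 0 that had not been called changed sign under some settings. Among the values for the results that lead the text, 122 stayed and 48 moved, and among the others 1076 stayed and 284 moved. A count that stayed could still change much. Under upper-quartile scaling the ASC counts went from 980 to 664 higher and from 926 to 1226 lower, and both were classed as staying. No paired analysis was possible because each group held 1 library. The motif alternatives were not run, and taking the highest entry of a symbol had no effect because no symbol was repeated.

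With a pseudocount of 0.1, FISC had 194 higher and 217 lower genes, and 46 genes were higher and 31 lower in both states. With 5, FISC had 26 and 35, ASC 576 and 306, activation in WT 2594 and 1113, and activation in iKO 925 higher. Then 8 genes were higher and 1 lower in both states, and Yy1 in ASC stood at −3.10.

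With a filter at 5 FPKM, 43 genes were higher in FISC and 13 in both states. Without a filter the ATP synthase median in ASC was 1.04, now apart from random lists (percentile 98.3). A threshold of 1.5-fold gave 361 higher and 462 lower genes in FISC, 2384 and 2268 in ASC and 2315 higher in iKO activation. At 4-fold these were 14 and 5 in FISC, 36 and 113 in ASC, 1241 and 727 in WT activation and 347 and 2313 in iKO activation.

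Median-centring gave 2337 higher and 2897 lower genes in WT activation and 2982 and 3042 in iKO activation. Upper-quartile scaling gave 2728 higher in iKO activation, and sums without Mir762 gave 2771 and 3282.

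With 5 expression bins, complexes II to IV (0.86, percentile 99.7) and ATP synthase (1.04, percentile 99.9) stood apart in ASC. Centring on locus length left 631 higher genes in ASC and medians of 0.80 for complex I, 0.47 for complexes II to IV and 0.59 for ATP synthase.

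The share of peaks near a locus end was 27.3% within 1 kb, 37.1% within 5 kb, 47.7% for the higher-scoring peaks and 82.6% for peaks with q of 0.05 or less. Bound genes of that last class had a FISC median of 0.0222, just above the central 95% of random sets, but at percentile 96.2 and inside it with locus length matched too.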

Other observations

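All tests below were chosen after the patterns they address had been seen. The predictions for the pooled, glycolysis and G2/M tests on locus length and for the further NF-kB targets were written before their own values were seen. Those for transcript size, single complexes, the citric acid cycle, chromosome Y and immune cells were written after.

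Genes of the unfolded protein response list, which did not stand apart in WT activation (percentile 5.03), went both ways. Asns, asparagine synthetase, stood at 5.27 FPKM in FISC WT and 204 in ASC WT, while the endoplasmic reticulum genes Herpud1 (621 and 48.4) and Dnajb9 (166 and 20.8) were lower after activation. Antioxidant genes stood apart on the higher side after activation with a median of 1.38, although Gpx3 went from 2221 to 64.7 FPKM. In freshly isolated cells Hmox1, heme oxygenase, stood at 1352 FPKM in WT and 804 in iKO, and Mthfd2, of mitochondrial folate metabolism, at 91.8 and 49.8. Sterol genes differed in ASC at single members, with Idi1 at 6.52 and 1.51 FPKM in WT and iKO and Pmvk at 10.5 and 24.9. Partners of YY1 stayed within 2-fold in both states, as Suz12 at 40.3 and 23.9 FPKM and Uchl5 at 35.9 and 67.7 in ASC.

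In activated cells the iKO ratio was higher for genes of short loci and lower for long ones, and part of the metabolic pattern may follow this trend. Among random lists matched on expression and locus length, the 81 genes of oxidative phosphorylation pooled had a median above all lists (1.02, percentile 100) and complex I alone lay at percentile 99.97, which argues against locus length as the whole cause there, while complexes II to IV at 77.8 and ATP synthase at 95.7 lay within the range that locus length gives. Glycolysis (percentile 0.11) and G2/M genes (percentile 0) stayed below length-matched lists. Citric acid cycle genes, at a median of 0.0290, did not share the shift, so it did not take in all mitochondrial genes. That value lay inside the range of lists also matched on locus length (percentile 12.3) and was known before its prediction was written. Mitochondrial ribosomal proteins, at 0.79 (percentile 99.89 among such lists), did share the shift. A cause common to mitochondrial genes is therefore not decided. Cytosolic ribosomal protein genes at 1.09, which encode small proteins with another function, went as far as complex I. They too stood above lists matched on expression and locus length (percentile 99.2). Their median was known before the prediction on transcript size was written, and transcript length was not measured, so it does not count as support. A trend with transcript size remains an untested candidate explanation, whether from RNA or library quality or from the state of the cells. Loss of Yy1 itself, the design's biological difference, stays open and cannot be separated from the library with 1 per group.

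The 3 strongest peak regions lay on chromosome Y before its first listed gene and span about the length of a mitochondrial genome, with 12743 bp covered, and the list held 0 peaks under the mitochondrial name. Whether these are mitochondrial reads listed under another chromosome name was left open. All 3 chrY peaks lay before the first gene, but that is the observation that raised the question and does not count as support. No sequence was compared and no biological explanation was tested.

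Lower chemokines in the freshly isolated iKO library may belong to a wider group of NF-kB targets. Of 27 other measured targets 23 lay below 0, with a median of −0.51 under all random lists (percentile 0), among them Nfkb1 itself (456 and 217 FPKM), Ccl2 (538 and 262) and Lif (59.9 and 27.4), while Tnfaip3 stood at 104 and 128. The list was drawn up after the chemokines had been named. Fewer immune cells as the source were left undecided by 5 low markers at percentile 52.5, among them Lyz2 at 2.82 and 2.39 FPKM. Dissociation and sorting of 2 separate cell preparations, or the partial decrease of Yy1 in this library, stay open as untested.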
